A study of Mus musculus with 12 samples.

How the data were processed

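Poly(A) RNA was measured in the livers of 12 mice, with 3 samples in each of 4 groups (control, MASH, EE and resmetirom). Per the labels' protocols, RNA was taken up in TRIzol, libraries were stranded mRNA libraries, and they were read as 150-base pairs on a NovaSeq X Plus, and the study ran 12 weeks, of which the last 4 were dosing. The submitters' processing notes name fastp for read trimming and the genome build GRCm39, without versions. The aligner, the counting tool, the annotation release and the counting strand are not given in the sources used here.

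The deposited table holds expected counts per Ensembl gene, which the authors made from the reads of each library, and they were not scaled to a common total before deposit. It has 28036 genes and 12 columns, all of them used, and between 91.5% and 93.3% of the values of a column are whole. The counts were rounded to whole numbers. Symbols came from a mouse gene table of an older genome build (GRCm38), which named 22603 of the identifiers, and 5433 have no symbol. Transcript lengths and GC content came from the same annotation, and no coordinates were used. At the library totals, 1 CPM before scaling stands for 17.3 to 21.8 counts, depending on the library. Lower bounds on a fold against a group with 0 counts use a floor of 3 counts over the group and cover counting error only.

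Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, scaling by the trimmed mean of M values, robust quasi-likelihood F test). All 12 libraries shared 1 fit with 8 residual degrees of freedom, and the adjusted p (Benjamini-Hochberg) had to lie below 0.05 over the 13988 tested genes. The biological coefficient of variation was 0.334. Every adjusted p of a gene is from edgeR unless another tool is named. The SE of a log2 fold change is its size divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 tested genes. There were 47 lists (27 functional and 20 of cell type markers, of which 41 had enough tested genes). Of their symbols 834 were found directly, 1 by a synonym and 9 not at all. A list was also tested with the correlation estimated from the data and with fry, a rotation test of limma. Within a list, members were also tested with the adjustment over the list alone.

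The comparisons, tests, lists and the rule for naming genes were chosen before the data were examined. For each comparison, the rule named up to 5 genes with the highest and 5 with the lowest log2 fold change among changed genes with no overlap between groups and a mean of at least 1 CPM, leaving out unnamed models and pseudogenes. Chance alone separates 3 against 3 samples of a gene in 10% of cases. The rule also named up to 4 members of each list with the smallest p, and 26 fixed genes of thyroid hormone response, lipid metabolism, fibrosis and inflammation, of which 24 were tested. Not every gene the rule allows is reported. Of the fixed genes, 0 passed edgeR in 5 of the comparisons and 3 did in resmetirom against control.

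The alternatives were scaling by relative log expression or by the upper quartile, DESeq2 1.42.0, limma voom, no filter, a filter at a mean of 1 CPM, a fit of only the compared groups, a replicate block, the same calls limited to a log2 fold change of at least 1, and leaving out each library in turn. After seeing the data 11 more were added: no scaling factors beyond the library totals, both outlying libraries left out, voom with quality weights, mitochondrial genes removed, offsets for transcript length and GC content, the combination of offsets with both libraries left out and with only the compared groups, the replicate block in only the compared groups (without and with offsets), and list tests in only the compared groups (without and with the block). Genes changed in more than 1 comparison were counted beside 40 simulations of unchanged groups, which draw each liver on its own, MASH livers included, and hold no pairing.

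The fits named here were run on simulated data with 100 genes changed 2-fold and 100 4-fold. In the fit of all 12 libraries, 4% to 14% of the 2-fold and 63% to 86% of the 4-fold changes were called, with 2 to 6 unchanged genes called. In EE and MASH alone, 72% and 92% were called with 16 unchanged genes, also with offsets. A block gave 72% and 93% with 30. For EE against MASH in all 12 libraries, DESeq2 called 38% and 91% with 32 unchanged genes, limma voom 15% and 81% with 4, also with quality weights, and edgeR with other scalings, no scaling factors, the block or offsets 12% to 14% and 84% to 86% with 6 to 8. Lists of 25 changed or unchanged genes were tested with camera (preset and estimated correlation) and fry. An estimated correlation gave p up to 0.000446 and from 0.0684, and fry up to 0.000176 and from 0.00762. Filters, left-out libraries, removed mitochondrial genes and other fits of 2 groups were not tested so. Offsets, blocks, quality weights and list tests had no simulated trend, pairs, weak library or gene correlation to act on. In 12 pairs checked, no library copied another. The labels give no batch, and p-values measure only the spread between the 12 samples. The labels do not say that a replicate number marks a shared litter, batch or day, and the fits chosen before the data were examined have no block. In a check of the deviations from the group means, same-numbered MASH and EE livers correlated at 0.19, 0.158 and 0.149 and the other pairs of MASH and EE livers at −0.0991 to −0.0495. Over all 18 same-numbered pairs values ran from −0.341 to 0.26, with 8 above 0.1, and other pairs reached 0.477. The pairing for EE against MASH was read from the livers the block tests, not the labels, so block counts cannot show it. Its values with a block are given where they differ. Tables used Python 3.11.15 with pandas 2.3.3 and figures matplotlib 3.10.9.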

Results

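Liver RNA was sequenced from 12 C57BL/6J mice, an inbred laboratory strain, in 4 groups of 3. Control mice ate normal chow, and the other groups were made with a high-fat diet as a model of metabolic dysfunction-associated steatohepatitis (MASH), a fatty liver disease with inflammation. After 8 weeks, a treated group received Eleutheroside E (EE), a plant lignan glycoside, by mouth at 100 mg/kg, and another received resmetirom, an agonist of thyroid hormone receptor beta, at 3 mg/kg. Dosing lasted 4 weeks, while control and MASH mice received 0.5% CMC-Na as vehicle. Each library is written as its group and replicate number, such as MASH 1. The library totals ranged from 17297864 to 21793311 counts, and 13988 genes had enough counts to be tested. Levels are given as CPM (counts scaled to a common library size by the trimmed mean of M values) with the SD over n = 3 livers, and fold changes as log2 values with their SE. Genes are named by symbol, and the files give each as an Ensembl identifier, such as ENSMUSG00000029638 for Glcci1, ENSMUSG00000030934 for Oat and ENSMUSG00000055254 for Ntrk2.

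The livers of a group were not equally alike. Mitochondrially encoded transcripts took 35.4% of the counts of control 1 and 2.40% to 4.38% of those of the other 11 libraries. The major urinary proteins (Mup), abundant secreted proteins of mouse liver, took 35.7% of resmetirom 2 and 3.33% to 16.0% elsewhere. Across genes, log2 CPM of the 3 MASH livers correlated at 0.979 to 0.982 and of the 3 EE livers at 0.978 to 0.980. Control 1 correlated with the other controls at 0.892 and 0.893, while control 2 and control 3 correlated at 0.984. The 3 resmetirom livers correlated at 0.903 to 0.948. The median of the Kupffer cell markers (12 genes) was −2.28 log2 units from the MASH mean in control 1 and −0.03 and −0.30 in control 2 and control 3. In resmetirom 1, the medians of the cell cycle, extracellular matrix and Kupffer cell lists lay 2.87, 1.60 and 1.16 log2 units above the MASH mean, and that of the pericentral hepatocyte markers lay at −1.90.

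**Figure D1:**
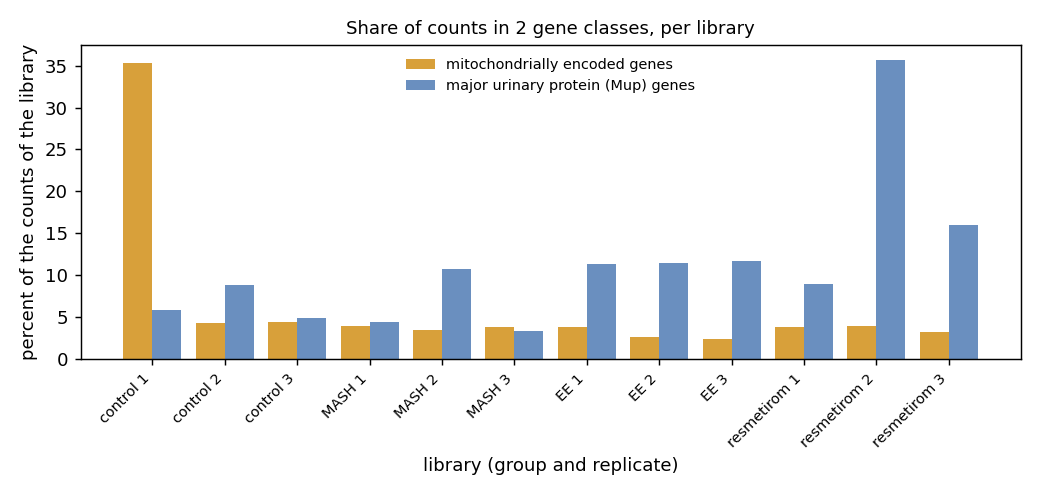
Percent of the counts of each library (horizontal axis, group and replicate) in mitochondrially encoded genes and in major urinary protein genes, as bars from 0. Control 1 holds 35.4% mitochondrial counts and resmetirom 2 holds 35.7% Mup counts.

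The comparison of MASH with control livers addresses what the diet model changed. Cyp2c55, a cytochrome P450 of drug and fatty acid metabolism, fell from 8.29 ± 1.87 CPM in controls to 0.965 ± 0.155 CPM in MASH (SD, n = 3 each; log2 fold change −3.10 ± 0.38 SE; edgeR adjusted p = 0.0177). Glcci1, a glucocorticoid-induced transcript, fell from 2.32 ± 0.772 to 0.0994 ± 0.024 CPM (−4.45 ± 0.48; adjusted p = 0.0114). Cyp2c55 and Glcci1 were the changed genes of the 13988 tested, both lower in MASH. Neither passed edgeR when the MASH and control livers were fitted without the other groups (0 genes, adjusted p = 0.11 each, with 1130 genes at an unadjusted p below 0.05), nor with offsets for transcript length and GC content in all 12 libraries (0 genes, 0.0611 each, with 1422), while limma voom called 1 gene (564 with quality weights), DESeq2 73, edgeR with no filter 34, with control 1 and resmetirom 2 left out 9 and with no scaling factors 1, Cyp2c55 then being lost (0.561). Glcci1 was lost with limma voom (0.0526) and Cyp2c55 with a replicate block (0.0536). In all, 1291 genes had an unadjusted p below 0.05 in the fit of all 12 livers, against 699.4 that chance gives.

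Fixed lists of genes were tested as groups by limma camera. Of the 19 tested lipid droplet and lipid uptake genes, 18 had a positive log2 fold change and the median was 0.83 (camera adjusted p = 3.55e-08, and 0.153 with an estimated correlation). None passed over all genes, and 7 rose when adjusted over the list alone. Cidec, a lipid droplet fusion protein, stood at 36.2 ± 21.5 CPM in MASH and 1.32 ± 1.06 CPM in controls (4.65 ± 1.03; adjusted p = 0.247). The fatty acid transporter Cd36 stood at 122 ± 21.4 against 41.6 ± 13.7 CPM, the droplet coat protein Plin2 at 802 ± 146 against 301 ± 163 CPM, and Pparg, a nuclear receptor of fat storage, at 15.1 ± 4.52 against 7.03 ± 0.789 CPM (adjusted p = 0.519, 0.508 and 0.512). Of 28 genes of fatty acid oxidation, 26 were positive (median 0.61, camera adjusted p = 5.75e-08, and 0.385 with an estimated correlation), and none passed singly or adjusted over the list alone. Vnn1, a target of PPAR alpha, stood at 120 ± 12.8 against 37.5 ± 5.08 CPM, and Fgf21, a liver hormone, at 5.54 ± 1.76 against 1.56 ± 0.0583 CPM (adjusted p = 0.51 and 0.535). Of 25 cholesterol synthesis genes, 23 were positive (median 0.48, camera adjusted p = 5.75e-08, and 0.522 with an estimated correlation), with 1 higher when adjusted over the list alone. The list median from the MASH mean was −1.13 log2 units in control 1 and −0.43 and −0.07 in control 2 and control 3, and with control 1 and resmetirom 2 left out the median fold change was 0.26 (camera adjusted p = 0.00169). Mvd, an enzyme of the mevalonate pathway, stood at 34.8 ± 5.93 against 14.9 ± 1.73 CPM (adjusted p = 0.392). Fatty acid synthesis rose with a median of 0.36 over 20 genes (camera adjusted p = 0.00754, and 0.698 with an estimated correlation), though not without control 1 (0.407) or MASH 3 (0.0654). Elovl5, a fatty acid elongase, stood at 834 ± 99.2 against 379 ± 29.3 CPM. Apoa4, an apolipoprotein, stood at 1420 ± 533.8 against 155 ± 28.9 CPM (3.19 ± 0.53; adjusted p = 0.16).

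Of 27 genes of amino acid metabolism and the urea cycle, 22 had a negative log2 fold change (median −0.38, camera adjusted p = 2.36e-05, and 0.522 with an estimated correlation), and 2 fell when adjusted over the list alone. Cth, which makes cysteine, stood at 192 ± 27.8 against 363 ± 92.4 CPM. Of 13 periportal hepatocyte markers, 12 were negative (median −0.60, camera adjusted p = 2.36e-05, and 0.0462 with an estimated correlation), and 1 fell when adjusted over the list alone. The glutaminase Gls2 stood at 195 ± 32.3 against 375 ± 64.7 CPM, and the urea cycle enzyme Ass1 at 1968 ± 371.1 against 3269 ± 386.6 CPM (adjusted p = 0.244 and 0.512). Of 25 drug metabolism genes, Cyp2c55 fell and the other 24 did not pass. When adjusted over the list alone 4 fell and 1 rose, and the median was −0.44 (camera adjusted p = 0.00382, and 0.266 with an estimated correlation; 0.0817 without control 3). Ces2a, a carboxylesterase, stood at 111 ± 14.7 against 526 ± 173 CPM. Cyp3a11 stood at 465.3 ± 183.8 against 3398 ± 1026 CPM and Cyp2b9 at 40.6 ± 37.8 against 0.252 ± 0.314 CPM, levels that are uncertain because near-identical genes can share their reads. The NRF2 targets fell (median −0.11, camera adjusted p = 0.0379, and 0.698 with an estimated correlation), but did not pass without any of control 1, control 2, control 3, MASH 1, MASH 2 or resmetirom 1 (0.0995, 0.072, 0.0635, 0.0957, 0.257 and 0.0529).

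Among cell types and inflammation, the monocyte and macrophage markers rose (median 0.69, camera adjusted p = 0.00074), as did the cell cycle list (0.97; 0.00124), each with an adjusted p of 0.698 with an estimated correlation. Mcm6, a replication helicase subunit, stood at 4.73 ± 1.11 against 2.30 ± 0.398 CPM. The Kupffer cell markers rose (median 0.52, camera adjusted p = 0.00146, and 0.698 with an estimated correlation), but not without control 1 (0.353). The interferon response (median 0.44; 0.00919), MHC class II (0.55; 0.0302), acute phase (0.14; 0.0282) and extracellular matrix lists (0.38; 0.0337) rose, with adjusted p = 0.698, 0.698, 0.643 and 0.705 with an estimated correlation. The interferon list did not pass without control 3 (0.0735) or MASH 3 (0.102), and MHC class II without control 3, MASH 1 or MASH 3 (0.149, 0.0665 and 0.318). The acute phase list did not pass without control 3 (0.0992) or MASH 3 (0.185), and the extracellular matrix list without control 2, MASH 1 or MASH 3 (0.316, 0.0846 and 0.174). Col1a1, a main fibrillar collagen of scar tissue, stood at 15.8 ± 5.78 against 9.20 ± 1.82 CPM (adjusted p = 0.765). Gpnmb and Trem2, genes of lipid-associated macrophages, stood at 4.64 ± 3.29 against 0.147 ± 0.186 CPM and 1.78 ± 0.316 against 0.301 ± 0.204 CPM (adjusted p = 0.519 and 0.527).

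Male-biased liver genes (median −0.48, camera adjusted p = 0.0018), the circadian clock (−0.38; 0.0106) and hepatocyte markers (−0.43; 0.0304) fell, with adjusted p = 0.698, 0.522 and 0.385 with an estimated correlation. The male-biased list did not pass without control 2 (0.0761) or MASH 3 (0.0917), the clock list without control 2 (0.112) or control 3 (0.0712), and the hepatocyte list without control 1, control 2 or control 3 (0.0541, 0.0719 and 0.0964). Nr1d1, a repressor of the clock, stood at 60.5 ± 8.42 against 137 ± 34.9 CPM. The 13 mitochondrially encoded genes had a median of −2.93 (camera adjusted p = 5.53e-08, and 0.522 with an estimated correlation), and all 13 fell when adjusted over the list alone. Without control 1 and resmetirom 2 their median was −0.32 (camera adjusted p = 0.011). The nuclear genes of oxidative phosphorylation (median −0.30; 0.0304) and erythroid markers (−1.45; 0.0304) fell, each with adjusted p = 0.698 with an estimated correlation. Neither passed without control 1 (0.924 and 0.41, the second in the other direction), nor without MASH 1 (0.0513 and 0.0665).

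In all, 21 of the 41 lists passed, 11 higher and 10 lower in MASH, and the periportal list alone passed with an estimated correlation. Cyp2c55 was the 1 member of these lists that passed over all genes. With control 1 and resmetirom 2 both left out, 11 lists passed and 11 of the 21 did not, namely monocytes and macrophages (median 0.49, camera adjusted p = 0.0521), the cell cycle (0.81; 0.0684), Kupffer cells (0.38), fatty acid synthesis (0.254), extracellular matrix (0.0585), acute phase (0.117), MHC class II (0.0751), NRF2 targets (0.0881), hepatocytes (0.0719), oxidative phosphorylation (0.954) and erythroid cells (0.38). The median of the interferon list was then 0.28, that of Kupffer cells 0.18, of hepatocytes −0.20, of fatty acid synthesis 0.00 and of oxidative phosphorylation −0.02. The count of changed genes was 0 without MASH 1, MASH 2, MASH 3 or control 2 and 1 without control 3, EE 1 or EE 3. It was 3 without resmetirom 3, 4 without control 1, 5 without EE 2 or resmetirom 1, and 6 without resmetirom 2. Of the 12 fits that left out 1 library, Glcci1 passed in all but those without control 2, MASH 1, MASH 2 or MASH 3 (adjusted p up to 0.204). Cyp2c55 passed in 5 and not without these 4, control 3, EE 1 or EE 3 (up to 0.298).

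**Figure D2:**
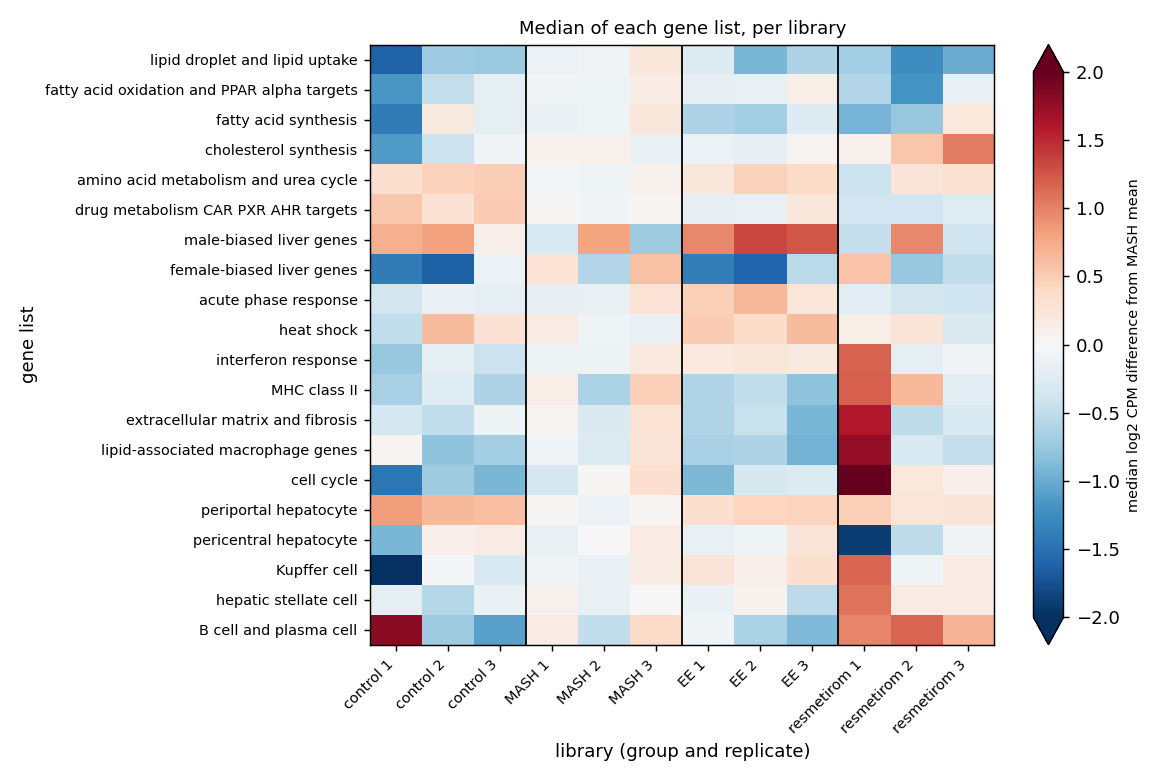
Median log2 CPM difference from the mean of the MASH libraries over the genes of 20 fixed lists (vertical axis) in each of the 12 libraries (horizontal axis), with red for higher and blue for lower medians. The cell cycle median of resmetirom 1 is 2.87 and the Kupffer cell median of control 1 is −2.28.

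The comparison of EE with MASH livers addresses what Eleutheroside E did in the diet model. Glcci1 rose from 0.0994 ± 0.024 CPM in MASH to 1.67 ± 0.3 CPM with EE (SD, n = 3 each; log2 fold change 3.99 ± 0.48 SE; edgeR adjusted p = 0.0348), toward the control level of 2.32 ± 0.772 CPM. It was the 1 changed gene in the fit of all 12 livers, in which 1048 genes had an unadjusted p below 0.05. It did not pass with length and GC offsets in all 12 libraries (0 genes, adjusted p = 0.321, with 903 genes at an unadjusted p below 0.05) or with limma voom (0 genes, 0.297, with 1085, and 1340 genes with quality weights), and DESeq2 called 23 genes, edgeR with no filter 8 and with control 1 and resmetirom 2 left out 67. With a replicate block, 5 genes changed, among them Glcci1 (0.0349), Selenbp2 (0.0469) and Cyp2b9 (0.0308). When the 3 EE and 3 MASH livers were fitted without the other groups, an alternative chosen before the data were examined, 746 genes changed, 391 higher and 355 lower. With offsets for transcript length and GC content, added after seeing the data, the fit of these 6 livers gave 183 genes, 99 higher and 84 lower. With a replicate block in this fit, also added after seeing the data, 2745 genes changed, 1400 higher and 1345 lower, and with both 1650, 821 higher and 829 lower. An adjusted p given with EE and MASH alone is that of the fit of these 6 livers without a block. With the block, of the genes so given Selenbp2 (0.0219), Cd36 (0.0225) and Fasn (0.00387) also passed and Pck1 (0.118) did not, and with block and offsets Pparg (0.0546), Col1a1 (0.0574), Igfbp2 (0.0567) and Selenbp2 (0.0587) did not.

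All 23 tested male-biased liver genes had a positive log2 fold change with EE (median 1.19, camera adjusted p = 7.49e-11, and 0.535 with an estimated correlation). None passed over all genes or when adjusted over the list alone. Selenbp2 stood at 1386 ± 751.8 CPM with EE and 191.4 ± 197.9 CPM in MASH, and Susd4 at 46.8 ± 12.2 against 18.9 ± 5.44 CPM (adjusted p = 0.595 each, and 0.14 and 0.035 with EE and MASH alone). With offsets in that fit, the adjusted p of Susd4 was 0.0865, and with a block as well 0.000278. Female-biased genes fell (median −1.06 over 9 genes, camera adjusted p = 0.0136, and 0.572 with an estimated correlation; −2.03 over a longer list of 11 genes with control 1 and resmetirom 2 left out), though not without MASH 3 (0.0799). Abcd2, a peroxisomal fatty acid transporter, stood at 6.41 ± 1.46 against 25.9 ± 5.08 CPM (adjusted p = 0.626, and 0.0082 with EE and MASH alone). All 14 heat shock genes were positive (median 0.46, camera adjusted p = 4.17e-05, and 0.535 with an estimated correlation), and none passed singly or adjusted over the list alone. Dnajb1, a co-chaperone, stood at 39.8 ± 12.8 against 18.8 ± 2.83 CPM.

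Lipid droplet genes fell (median −0.63 over 19 genes, camera adjusted p = 0.000138, and 0.535 with an estimated correlation), 7 of them when adjusted over the list alone. Cidec stood at 4.49 ± 2.69 CPM with EE and 36.2 ± 21.5 CPM in MASH, Cd36 at 35.6 ± 16.4 against 122 ± 21.4 CPM, and Pparg at 6.51 ± 1.06 against 15.1 ± 4.52 CPM (adjusted p = 0.595, 0.598 and 0.595, and 0.077, 0.066 and 0.032 with EE and MASH alone). Fatty acid synthesis fell (median −0.55 over 20 genes, camera adjusted p = 0.00379, and 0.612 with an estimated correlation), with 1 gene lower when adjusted over the list alone, but not without MASH 3 (0.0799). The elongase Elovl6 stood at 40.5 ± 3.81 against 88.9 ± 11.2 CPM and Fasn, which makes palmitate, at 370 ± 147 against 909 ± 247 CPM (adjusted p = 0.582 and 0.627, and 0.0082 and 0.088 with EE and MASH alone). Angptl4, an inhibitor of lipoprotein lipase, stood at 185 ± 30.8 against 63.4 ± 7.87 CPM (1.54 ± 0.35; adjusted p = 0.582, and 0.0082 with EE and MASH alone). Pck1, the rate-limiting enzyme of gluconeogenesis, stood at 2383 ± 643.1 against 1123 ± 239.4 CPM and Igfbp2 at 301 ± 57.1 against 153 ± 10 CPM (0.042 and 0.022 with EE and MASH alone, and 0.103 and 0.0609 with length and GC offsets as well).

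Extracellular matrix genes fell, with 30 of 33 negative (median −0.64, camera adjusted p = 0.000138, and 0.612 with an estimated correlation) and none past the test singly or adjusted over the list alone. Col1a1 stood at 4.68 ± 0.954 CPM with EE and 15.8 ± 5.78 CPM in MASH (adjusted p = 0.638, and 0.029 with EE and MASH alone), and the crosslinking enzyme Loxl1 at 0.931 ± 0.315 against 2.46 ± 0.263 CPM. Fitted as EE and MASH alone, 7 of the 30 genes of this list tested there fell, beside 355 of all 13248 genes, and 3 fell with length and GC offsets as well. The lists of lipid-associated macrophages (median −0.77, camera adjusted p = 0.00937), MHC class II (−0.72; 0.00965) and cytokines and chemokines (−0.57; 0.0429) fell, with adjusted p = 0.612, 0.612 and 0.703 with an estimated correlation, and none of the 3 passed without MASH 3 (0.0799, 0.243 and 0.263). Adjusted over the list alone, 3 macrophage genes fell and 1 rose. Ccr2, a receptor of recruited monocytes, stood at 0.265 ± 0.178 against 1.75 ± 0.718 CPM. The markers of cholangiocytes (−0.91; 0.0329), large vessels (−0.59; 0.0379) and portal fibroblasts (−1.20; 0.0419) fell, with adjusted p = 0.535, 0.535 and 0.612 with an estimated correlation. Cholangiocyte markers did not pass without MASH 1 (0.142) or EE 1 (0.212), and large vessel markers did not without MASH 3, EE 1, EE 2 or resmetirom 2 (0.276, 0.112, 0.086 and 0.0501). Portal fibroblast markers, a list of 5 tested genes, passed without MASH 2, EE 3, resmetirom 1 or resmetirom 3 and lost the call without any of the other 8 libraries (0.0507 to 0.188). With EE and MASH alone, cholangiocyte and large vessel markers did not pass (0.114 and 0.0878), and with a replicate block portal fibroblast markers did not either (0.0537).

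The amino acid list rose (median 0.33, camera adjusted p = 0.000138), as did the unfolded protein response (0.44; 0.00182) and the periportal markers (0.33; 0.00266), with adjusted p = 0.537, 0.537 and 0.244 with an estimated correlation. Herpud1, of endoplasmic reticulum protein degradation, stood at 611 ± 108 against 235 ± 26.1 CPM (1.38 ± 0.41; adjusted p = 0.595, and 0.0082 with EE and MASH alone). The acute phase list rose (0.47; 0.00293), as did the interferon list (0.13; 0.00293) and nuclear oxidative phosphorylation genes (0.24; 0.00377), with adjusted p = 0.535, 0.612 and 0.686 with an estimated correlation. Itih3, a plasma inhibitor chain, stood at 851 ± 76.8 against 477 ± 20.9 CPM and Irf7, a regulator of interferon genes, at 55.5 ± 12.1 against 28.1 ± 2.91 CPM (0.018 and 0.027 with EE and MASH alone). Hepatocyte markers rose (0.45, camera adjusted p = 0.0331, and 0.535 with an estimated correlation; 0.0825 without MASH 3), with the plasma protein Ahsg at 6519 ± 1133 against 3833 ± 126.1 CPM. NRF2 targets (−0.21; 0.021) and p53 targets (−0.40; 0.0382) fell, with adjusted p = 0.612 and 0.675 with an estimated correlation. NRF2 targets did not pass without MASH 3 (0.32) or EE 2 (0.259), and p53 targets without MASH 1, MASH 3, EE 2 or EE 3 (0.0636, 0.0799, 0.0698 and 0.115).

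No member of the lists passed edgeR over all genes in the fit of all 12 livers. In all, 21 of 41 lists passed, 9 higher and 12 lower with EE, and 0 passed limma camera with an estimated correlation, while fry, a rotation test within a list, called the periportal list (0.00805). Without MASH 3, 11 lists passed. With control 1 and resmetirom 2 both left out 13 did, and the lists of cytokines (0.0924), lipid-associated macrophages (0.0941), NRF2 targets (0.0562), p53 targets (0.0718), MHC class II (0.0718), portal fibroblasts (0.166), cholangiocytes (0.0912) and large vessels (0.0802) did not. The count of changed genes was 1 without control 1, control 3, resmetirom 1 or resmetirom 2 and 0 without any of the other 8. Among these, the adjusted p of Glcci1 reached 0.529 without MASH 3.

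**Figure D3:**
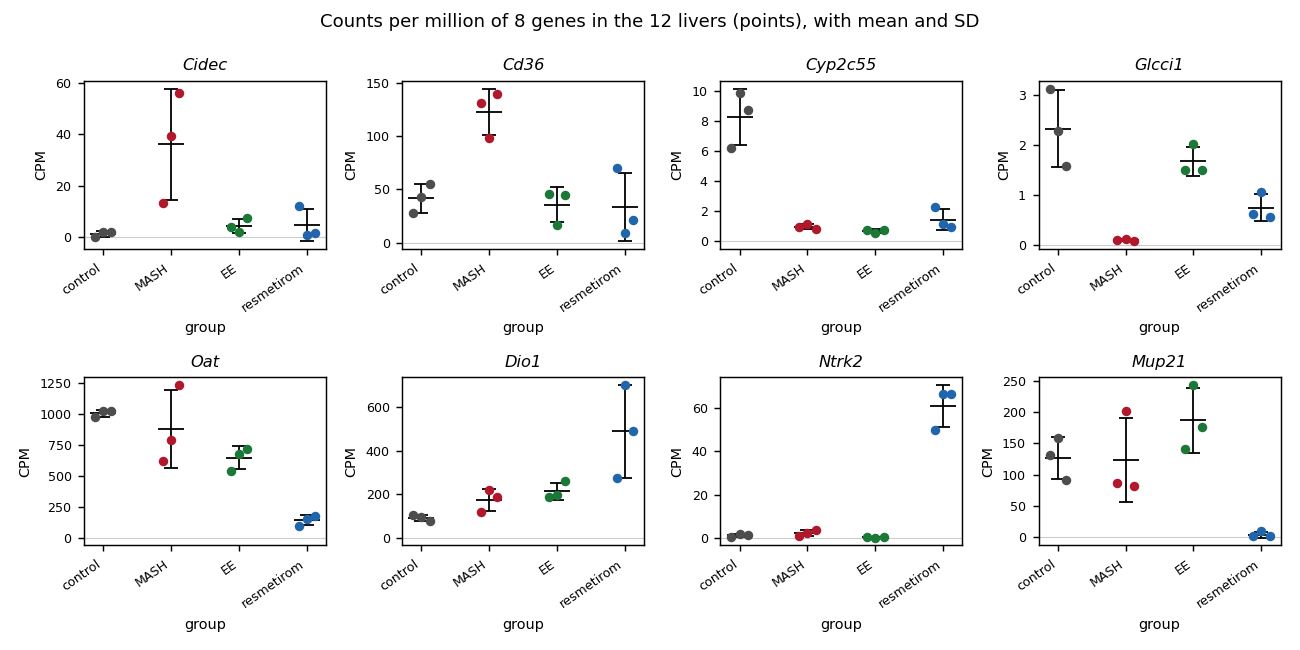
CPM of 8 genes in the 12 livers (points) by group, with the group mean and SD as bars on linear axes from 0. Glcci1 lies at 0.0781 to 0.125 CPM in the MASH livers and Ntrk2 at 49.8 to 66.7 CPM in the resmetirom livers.

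The comparison of resmetirom with MASH livers addresses the effect of the comparator drug in the same model. Oat, an ornithine aminotransferase of pericentral hepatocytes, fell from 877 ± 315 CPM in MASH to 138 ± 39.4 CPM (SD, n = 3 each; log2 fold change −2.67 ± 0.31 SE; edgeR adjusted p = 0.0089). Abcc3, an efflux pump for bile acid conjugates, fell from 289 ± 67.8 to 18.6 ± 13.7 CPM, and the droplet coat gene Plin4 from 12.9 ± 6.54 to 1.22 ± 0.515 CPM (adjusted p = 0.0155 and 0.0245). Igfbp2, an insulin-like growth factor binding protein, rose from 153 ± 10 to 700 ± 241 CPM, and Sort1, a sorting receptor in lipoprotein secretion, from 16.0 ± 3.95 to 49.1 ± 8.46 CPM (adjusted p = 0.0155 each). In all, 93 genes changed, 47 higher and 46 lower, and 2102 had an unadjusted p below 0.05. When the resmetirom and MASH livers were fitted without the other groups, edgeR called 0 genes (smallest adjusted p = 0.0552, with 1935 genes at an unadjusted p below 0.05), while in all 12 livers limma voom called 100 (834 with quality weights) and DESeq2 622. That fit of 6 livers gave 14 genes with length and GC offsets (Cfd and Mup21 of those named below) and 27 with a replicate block (Oat, Cfd, Wfdc16, Ptgds, Dnaic1, Mup21 and Cyp2b9 of those named), and in all 12 edgeR called 243 with no filter, 467 with control 1 and resmetirom 2 left out and 38 with no scaling factors.

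Among the genes with the greatest changes, Cfd, the adipsin gene of fat cells, had 0 counts in all 3 resmetirom livers against 25.8 ± 13.1 CPM in MASH, at least 510-fold lower with a floor of 3 counts over the group (adjusted p = 0.0155). Wfdc16 stood at 7.76 ± 5.12 CPM and had 0 counts in MASH, at least 165-fold higher (adjusted p = 0.0155). Ptgds, a prostaglandin D synthase (6.93 ± 1.15), the axonemal dynein gene Dnaic1 (6.73 ± 1.25), the linker histone gene H1fx (5.96 ± 1.00) and the elastase gene Cela2a (5.73 ± 1.07) rose on the log2 scale (adjusted p = 0.0245, 0.0379, 0.0245 and 0.0392). Cela2a had 246 counts in resmetirom 2 and 27 to 47 in the other resmetirom livers. Themis, a signalling gene of T cell development, fell from 5.93 ± 3.69 to 0.131 ± 0.0725 CPM (adjusted p = 0.0155). Mup21 fell from 124 ± 67.5 to 4.15 ± 4.58 CPM, Cyp2b9 from 40.6 ± 37.8 to 0.479 ± 0.487 CPM and the antisense gene Hectd2os from 56.4 ± 19.6 to 1.82 ± 1.57 CPM (adjusted p = 0.0155, 0.0392 and 0.0245). These 3 are uncertain, since Mup21 and Cyp2b9 share reads with near-identical genes and the strand counted for Hectd2os is not given.

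Of 18 tested genes responsive to thyroid hormone, Idh3a, a citric acid cycle enzyme, rose from 26.7 ± 1.96 to 56.9 ± 13.4 CPM (1.09 ± 0.19; adjusted p = 0.0305) and the other 17 did not pass. Adjusted over the list alone 3 rose and 2 fell, and the list did not pass as a group (median 0.18, camera adjusted p = 0.5). Dio1, the deiodinase that is a classical target of the hormone, stood at 490 ± 214 CPM with resmetirom and 175 ± 50.8 CPM in MASH (1.48 ± 0.34; adjusted p = 0.074). Hr stood at 5.69 ± 5.06 against 1.47 ± 0.488 CPM and Fgf21 at 21.9 ± 19.9 against 5.54 ± 1.76 CPM (adjusted p = 0.236 and 0.24). Irs2, an insulin receptor substrate, rose from 10.1 ± 1.11 to 21.6 ± 2.43 CPM (adjusted p = 0.0439).

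Fatty acid oxidation genes fell, with 23 of 28 negative (median −0.47, camera adjusted p = 0.000115, and 0.762 with an estimated correlation). None passed over all genes, while 8 fell and 1 rose when adjusted over the list alone. Acadm, a dehydrogenase of mitochondrial oxidation, stood at 146 ± 46.3 against 346 ± 15.6 CPM and Vnn1 at 18.7 ± 13.8 against 120 ± 12.8 CPM (adjusted p = 0.0567 and 0.0523). Lipid droplet genes fell (median −0.81, camera adjusted p = 0.000165, and 0.762 with an estimated correlation). Of its 19 genes Plin4 fell and 18 did not pass, and 9 fell and 1 rose when adjusted over the list alone. Cidec stood at 4.84 ± 6.32 and Pparg at 5.38 ± 3.38 CPM (adjusted p = 0.18 and 0.111). Fatty acid synthesis fell (median −0.32, camera adjusted p = 0.0121, and 0.762 with an estimated correlation), though not without MASH 3 (0.0834) or resmetirom 1 (0.42). Cholesterol synthesis rose, with 22 of 25 positive (median 0.61, camera adjusted p = 0.000413, and 0.762 with an estimated correlation) and 3 higher when adjusted over the list alone, but not without resmetirom 3 (0.123). Mvk, the mevalonate kinase, stood at 61.8 ± 19.7 against 25.2 ± 3.04 CPM and Dhcr7 at 225 ± 71.6 against 111 ± 6.13 CPM (adjusted p = 0.0571 and 0.0949).

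Cell cycle genes rose, with 24 of 25 positive (median 1.70, camera adjusted p = 0.000165, and 0.762 with an estimated correlation), 10 of them when adjusted over the list alone, and did not pass without resmetirom 1 (0.483). Cdc20, an activator of mitotic exit, stood at 8.99 ± 12.2 against 0.974 ± 0.719 CPM and Cdk1 at 2.89 ± 2.4 against 0.774 ± 0.291 CPM (adjusted p = 0.155 each). Extracellular matrix genes (0.61; 0.0196) and stellate cell markers (0.60; 0.0328) rose, with adjusted p = 0.899 and 0.762 with an estimated correlation. Neither passed without MASH 2 (0.162 and 0.0767) or resmetirom 1 (0.0843, in the other direction, and 0.864). Col1a1 was 90.4 CPM in resmetirom 1 and 9.14 and 7.54 CPM in resmetirom 2 and resmetirom 3. Immediate early genes rose (0.88, camera adjusted p = 0.00294, and 0.762 with an estimated correlation; 0.308 without resmetirom 1), with 2 higher when adjusted over the list alone. Egr1 stood at 32.4 ± 21.5 against 4.89 ± 0.0985 CPM. Pericentral hepatocyte markers fell (−0.31, camera adjusted p = 0.00294, and 0.762 with an estimated correlation; 0.364 without resmetirom 1), among which Oat fell and the other 12 did not pass, with 2 lower when adjusted over the list alone.

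All 8 markers of B and plasma cells were positive (median 0.78, camera adjusted p = 0.00326, and 0.762 with an estimated correlation), with 3 higher when adjusted over the list alone. Ighm, the IgM heavy chain, rose from 6.21 ± 1.36 to 80.4 ± 60.3 CPM (adjusted p = 0.0439). The interferon list rose (0.31, camera adjusted p = 0.0328, and 0.883 with an estimated correlation), but not without MASH 1 (0.0766), MASH 2 (0.101) or resmetirom 1 (0.494, in the other direction). Of its 28 genes Bst2, an antiviral membrane protein, rose from 76.1 ± 7.82 to 204 ± 66.7 CPM (adjusted p = 0.0245). The chemokine gene Ccl9 rose from 21.0 ± 1.87 to 60.8 ± 20.2 CPM (adjusted p = 0.0273). Of 13 periportal markers Cdh1, the epithelial cadherin, rose from 24.4 ± 12.8 to 92.2 ± 23.2 CPM and Sult5a1 from 3.79 ± 1.89 to 31.6 ± 20.3 CPM (adjusted p = 0.0435 each), and the list did not pass as a group (camera adjusted p = 0.153). Nuclear oxidative phosphorylation genes (0.49; 0.00157) and the unfolded protein response (0.66; 0.0255) rose, each with adjusted p = 0.762 with an estimated correlation. The first did not pass without resmetirom 2 (0.904) and the second without MASH 3, resmetirom 1 or resmetirom 2 (0.126, 0.296 and 0.407). Without control 1 and resmetirom 2, their camera adjusted p was 0.981 and 0.533 (medians 0.06 and 0.12). Fatty acid oxidation, matrix, interferon and pericentral lists then passed (medians −0.29, 0.98, 0.59 and −0.81). The last 3 failed without resmetirom 1, kept here.

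In all, 13 of 41 lists passed, 9 higher and 4 lower, 5 without resmetirom 1 and 21 without resmetirom 3, and 0 passed limma camera with an estimated correlation or fry. The count of 93 genes was 42, 46 and 24 without EE 1, EE 2 and EE 3, 5, 1 and 4 without MASH 1, MASH 2 and MASH 3, 59 without control 2 and 32 without resmetirom 2. It was 431 without control 1, 163 without resmetirom 1 and 169 without resmetirom 3. Of the 12 fits that left out 1 library, Oat passed in all but that without MASH 2 (adjusted p = 0.051). Wfdc16, Cfd, Mup21, Abcc3, Sort1 and Igfbp2 passed in all but those without MASH 1, MASH 2 or MASH 3 (up to 0.0995), Hectd2os in all but these and EE 3 (0.0913), and Themis in all but MASH 2, MASH 3 and resmetirom 2 (0.0776). With no scaling factors H1fx, Cyp2b9, Plin4, Idh3a, Abcc3, Sort1, Irs2, Ccl9, Bst2, Cdh1 and Ighm were lost (0.0502 to 0.618). Also lost were with limma voom Ptgds, Dnaic1, H1fx, Cela2a, Cfd, Cyp2b9, Themis and Ighm (up to 0.214), with quality weights Cfd, Cyp2b9 and Themis (0.352) and with no filter Ptgds, Dnaic1, Cela2a, Cfd, Cyp2b9, Hectd2os, Ighm and Sult5a1 (0.135). With a replicate block Cela2a, Irs2, Ighm and Sult5a1 were lost (0.0827), with offsets Irs2, Bst2 and Sult5a1 (0.119), with control 1 and resmetirom 2 left out Cyp2b9 and Ighm (0.0554), and with offsets as well also Themis, Irs2 and Cdh1 (0.0743). Ptgds, H1fx and Ccl9 were lost without any MASH liver, EE 3 or resmetirom 2 (up to 0.147), and Plin4 also without resmetirom 3 (0.116). Bst2, Irs2, Dnaic1, Cela2a, Sult5a1, Idh3a, Ighm, Cdh1 and Cyp2b9 passed in 2 to 5 of these fits and in none without a MASH liver, an EE liver or resmetirom 2 (up to 0.199). Of these 9, some were also lost without control 2 (Dnaic1, Cela2a, Sult5a1, Idh3a, Ighm and Cdh1), control 3 (Idh3a, Ighm, Cdh1 and Cyp2b9), resmetirom 1 (Cdh1 and Cyp2b9) or resmetirom 3 (Irs2, Ighm and Cyp2b9).

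The comparison of EE with resmetirom addresses whether the treated groups differed. The compounds were given at different doses and are not structural analogs. Ntrk2, a neurotrophin receptor gene, stood at 0.377 ± 0.202 CPM with EE and 61.0 ± 9.7 CPM with resmetirom (SD, n = 3 each; log2 fold change −7.30 ± 0.58 SE; edgeR adjusted p = 0.000401), and at 0.603 to 3.75 CPM in the control and MASH livers. Oat was higher with EE, at 642 ± 93 against 138 ± 39.4 CPM, as was Cyp2c23, an arachidonic acid epoxygenase, at 296 ± 62.3 against 40.3 ± 20.2 CPM (adjusted p = 0.0185 and 0.0204). C8a, a complement component, was higher with EE at 632 ± 88.8 against 203 ± 14 CPM (adjusted p = 0.0241). In all, 43 genes differed, 21 higher and 22 lower with EE, and 1652 had an unadjusted p below 0.05. When the EE and resmetirom livers were fitted without the other groups 3 genes differed, of those named Ntrk2 (adjusted p = 0.00106) alone, 6 with length and GC offsets and 10 with a replicate block. In all 12 livers the count was 12 with no scaling factors (3 higher and 9 lower), 19 with a replicate block (10 and 9), 176 with no filter, 417 with control 1 and resmetirom 2 left out, 385 with DESeq2 (163 and 222) and 249 with limma voom and quality weights.

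Cfd was at least 256-fold higher with EE, at 13.0 ± 10.1 CPM against 0 counts, and Wfdc16 at least 129-fold lower, at 0 counts against 7.76 ± 5.12 CPM (adjusted p = 0.0292 and 0.0283). Abcc3 (3.45 ± 0.58) and Acpp (2.89 ± 0.53) were higher with EE, and Ptgds (−6.06 ± 1.09), H1fx (−5.27 ± 0.96) and the potassium channel gene Kcnk1 (−4.93 ± 0.91) were lower (adjusted p = 0.0416, 0.0477, 0.0463, 0.0473 and 0.0499). Mup21, uncertain as above, was at 187 ± 52 against 4.15 ± 4.58 CPM (adjusted p = 0.0162). Of 18 thyroid hormone responsive genes, Idh3a was lower with EE, at 25.6 ± 2.43 against 56.9 ± 13.4 CPM (adjusted p = 0.0416), the other 17 did not pass, and when adjusted over the list alone 5 were lower and 1 higher (median −0.31, camera adjusted p = 0.125). Dio1 stood at 213 ± 40.6 against 490 ± 214 CPM and Hr at 0.491 ± 0.467 against 5.69 ± 5.06 CPM (adjusted p = 0.171 and 0.101).

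Of 23 male-biased genes, Mup21 and C8a were higher with EE, 21 did not pass and 3 were higher when adjusted over the list alone (median 0.82, camera adjusted p = 1.25e-09, and 0.313 with an estimated correlation). The list median from the MASH mean was −0.48, 0.97 and −0.40 log2 units in resmetirom 1, resmetirom 2 and resmetirom 3 and 0.96 to 1.34 in the EE livers, and with control 1 and resmetirom 2 left out the median fold change was 1.59. Cyp4a12b stood at 100 ± 16.6 against 11.7 ± 13.2 CPM. All 33 extracellular matrix genes were negative (median −1.34, camera adjusted p = 1.45e-09, and 0.313 with an estimated correlation), 13 of them lower when adjusted over the list alone, with Loxl1 at 0.931 ± 0.315 against 6.22 ± 4.72 CPM and Col1a1 at 4.68 ± 0.954 against 35.7 ± 47.4 CPM. The list median from the MASH mean was 1.60 log2 units in resmetirom 1, −0.51 and −0.31 in resmetirom 2 and resmetirom 3, and −0.61, −0.45 and −0.91 in the EE livers. Cell cycle genes were lower (median −2.23, camera adjusted p = 1.93e-08, and 0.313 with an estimated correlation), 16 of 25 when adjusted over the list alone, with Ccnb2, a mitotic cyclin, at 0.296 ± 0.155 against 5.05 ± 6.62 CPM. Here the list median from the MASH mean was 2.87 in resmetirom 1, 0.22 and 0.11 in resmetirom 2 and resmetirom 3, and −0.89, −0.32 and −0.28 in the EE livers. Cholesterol synthesis was lower (−0.75; 1.08e-07) and fatty acid oxidation higher (0.62; 5.26e-08), each with adjusted p = 0.313 with an estimated correlation. Adjusted over the list alone, 7 of 25 cholesterol genes were lower, and 4 of 28 oxidation genes were higher and 1 lower. Acute phase genes were higher (0.74, camera adjusted p = 1.8e-06, and 0.313 with an estimated correlation), 7 of 25 when adjusted over the list alone, with Itih3 at 851 ± 76.8 against 389 ± 96 CPM and Lbp at 85.5 ± 12.3 against 45.2 ± 4.21 CPM.

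Lower with EE were also MHC class II (−1.24; 9.89e-06), B and plasma cell markers (−1.76; 2.66e-05), immediate early genes (−1.07; 0.000139) and portal fibroblast markers (−2.30; 0.000311), all with adjusted p = 0.313 with an estimated correlation. H2-Eb1 stood at 19.0 ± 1.69 against 51.8 ± 23.6 CPM, and Ighm was lower at 4.29 ± 2.15 against 80.4 ± 60.3 CPM (adjusted p = 0.124 and 0.0426). Higher with EE were the heat shock list (0.53; 8.61e-05) and the pericentral (0.54; 2.9e-05) and hepatocyte (0.26; 0.0232) markers, all with adjusted p = 0.313 with an estimated correlation. The lists of cytokines (−0.88; 0.000705), stellate cells (−0.55; 0.000731), p53 targets (−0.82; 0.00494), dendritic cells (−1.07; 0.00785) and lipid-associated macrophages (−1.34; 0.00813) were lower. Their adjusted p with an estimated correlation was 0.385, 0.343, 0.427, 0.313 and 0.429, and none of these 5 passed without resmetirom 1 (0.379, 0.178, 0.69, 0.439 and 0.849). The lists of amino acid metabolism (0.18; 0.00108), the circadian clock (0.58; 0.00304), gluconeogenesis (0.50; 0.0074) and bile acids (0.20; 0.0129) were higher, with adjusted p = 0.38, 0.313, 0.313 and 0.439 with an estimated correlation. None of these 4 passed without resmetirom 1 either (0.37, 0.0666, 0.0666 and 0.379). Cholangiocyte markers (−0.97; 0.0054), NRF2 targets (−0.34; 0.0245) and large vessel markers (−0.41; 0.042) were lower, with adjusted p = 0.313, 0.418 and 0.313 with an estimated correlation. Gstm3, a glutathione transferase of the NRF2 list, was lower at 16.5 ± 3.09 against 91.4 ± 33.8 CPM (adjusted p = 0.0416). Cholangiocyte markers did not pass without EE 1 (0.0531), NRF2 targets without EE 2, resmetirom 1 or resmetirom 2 (0.244, 0.218 and 0.111), and large vessel markers without EE 1, EE 2, resmetirom 1, resmetirom 2 or resmetirom 3 (0.0857, 0.109, 0.199, 0.0565 and 0.0512). With control 1 and resmetirom 2 both left out, the NRF2 (0.137) and large vessel (0.0641) lists did not pass, and the medians of the amino acid and hepatocyte lists were 0.31 and 0.43.

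In all, 25 of 41 lists passed, 10 higher and 15 lower with EE, and 0 passed limma camera with an estimated correlation or fry. The count of 43 genes was 8, 8 and 7 without EE 1, EE 2 and EE 3, 19, 18 and 20 without MASH 1, MASH 2 and MASH 3, 22 and 14 without control 2 and control 3, and 19 without resmetirom 2. It was 138 without control 1 and 130 without resmetirom 3. Ntrk2 passed in all 12 of these fits (highest adjusted p = 0.00806), as did Mup21 (0.048). With no scaling factors Oat, Cyp2c23, C8a, Abcc3, Acpp, H1fx, Kcnk1, Idh3a and Gstm3 were lost (0.098 to 0.248). Also lost were with limma voom Cfd, Acpp, Ptgds, H1fx, Kcnk1 and Ighm (up to 0.298), with quality weights Cfd, Acpp and H1fx (0.367), with no filter Cfd, Abcc3, Ptgds, Kcnk1 and Ighm (0.129), with the filter at 1 CPM Acpp, Ptgds, H1fx and Kcnk1 (0.0531) and with relative log expression Kcnk1 (0.05). With a replicate block the 10 named genes other than Ntrk2, Oat, Cyp2c23, C8a and Mup21 were lost (up to 0.0939), with offsets H1fx (0.0604), and with control 1 and resmetirom 2 left out Cfd (0.0502, and 0.0554 with offsets). Oat was lost without EE 2 or EE 3 and Cyp2c23 without these or resmetirom 2 (up to 0.0847 each). C8a and Wfdc16 were lost without any EE liver, control 3 or resmetirom 2 (0.122 and 0.112), and Cfd without control 3, MASH 3, EE 1, EE 3, resmetirom 1 or resmetirom 2 (0.108). Abcc3, Acpp, Ptgds, H1fx, Kcnk1, Gstm3, Ighm and Idh3a passed in 2 or 3 of these fits and in none without control 2, control 3, MASH 1, MASH 2 or any EE liver (up to 0.237). Without MASH 3 all 8 but Gstm3 were lost, without resmetirom 2 all but Abcc3, without resmetirom 1 Acpp, H1fx and Gstm3, and without resmetirom 3 Abcc3.

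The genes changed in more than 1 of these comparisons address how far each treatment moved the livers back toward control. Glcci1, lower in MASH, was the 1 gene that rose again with EE, the 1 with resmetirom and so the 1 both changed. All 3 calls use its MASH level, 0.0781 to 0.125 CPM, a few counts per liver. Of the 2 changed in MASH, 0 moved further from control. Independent lists of these sizes would share 0.000143, 0.00672 and 0.00336 genes. The MASH libraries are shared by each pair of comparisons, and 40 simulations of unchanged groups against the same MASH libraries gave at most 1, 0 and 0 shared genes. Across genes, log2 fold changes of MASH against control had covariances of −0.124 (simulated −0.105) with those of EE and of resmetirom against MASH. That of both treatments was 0.156 (simulated 0.105). The correlations were −0.328 (simulated −0.487), −0.261 (−0.49) and 0.377 (0.493), nearer to 0 than the simulated ones, while the covariances lay further from 0. The numbers of shared genes for EE, for resmetirom and for both treatments were 0, 0 and 0 with limma voom, with length and GC offsets or with only the compared groups fitted, and 0, 0 and 7 with a replicate block in the latter. They were 2, 2 and 3 with a replicate block in all 12 livers, 2, 6 and 4 with no filter, 1, 1 and 18 with control 1 and resmetirom 2 left out, 5, 15 and 10 with DESeq2 and 113, 48 and 258 with limma voom and quality weights. Without control 1, control 3, resmetirom 1 or resmetirom 2 the count for EE was 1, and it was 0 without any of the other 8 libraries. The count for resmetirom was 1 without those same 4, 2 without EE 2 or resmetirom 3 and 0 without any of the other 6. The count for both treatments was 1 without control 1, control 3 or resmetirom 1 and 0 without any of the other 9.

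The comparison of EE livers with controls addresses what still differed after treatment. Cyp2c55 remained low, at 0.671 ± 0.111 CPM against 8.29 ± 1.87 CPM in controls (SD, n = 3 each; log2 fold change −3.62 ± 0.39 SE; edgeR adjusted p = 0.0111). Cyp3a59, another cytochrome P450, was lower at 5.30 ± 2.04 against 32.5 ± 3.07 CPM, and Phip at 1.71 ± 0.365 against 7.95 ± 2.43 CPM (adjusted p = 0.0178 and 0.0399). Gsta2, a glutathione transferase with close paralogs that makes its level uncertain, and the noncoding gene Snhg11 were also lower (−2.87 ± 0.45 and −5.27 ± 0.81; adjusted p = 0.0387 each). All 14 changed genes were lower with EE, and 2257 had an unadjusted p below 0.05. When the EE and control livers were fitted without the other groups, edgeR called 0 genes (smallest adjusted p = 0.0739, with 1895 genes at an unadjusted p below 0.05), while in all 12 livers limma voom called 9 and edgeR 2 with length and GC offsets, all lower. Other settings called genes in both directions, DESeq2 82 higher and 385 lower, no filter 17 and 100, control 1 and resmetirom 2 left out 100 and 489, and limma voom with quality weights 960 and 1601. With no scaling factors edgeR called 0 genes (smallest adjusted p = 0.429). Snhg11 and Phip were lost with limma voom (0.0863 and 0.0685), Snhg11 with a replicate block (0.0587), Phip with the upper quartile (0.0501), all named genes but Cyp2c55 with offsets (up to 0.184), and Gsta2 and Phip with offsets when control 1 and resmetirom 2 were left out (0.0609 and 0.0809). The count was 1 without EE 1, 0 without EE 2 or EE 3, 3 without MASH 1 and 2 without MASH 2. It was 0 without control 2 or control 3, 69 without resmetirom 1, 36 without resmetirom 2 and 2 without resmetirom 3. Dio1 stood at 213 ± 40.6 against 90.9 ± 14.5 CPM (adjusted p = 0.138), and none of the 24 tested genes that were fixed for every comparison passed edgeR. Cyp2c55 was lost without any EE liver, control 2 or control 3 (up to 0.152) and Cyp3a59 without EE 2, EE 3, control 2 or control 3 (0.277). Snhg11, Gsta2 and Phip passed in 3 of the 12 fits that left out 1 library and in none without control 2, control 3, MASH 1, MASH 2, an EE liver or resmetirom 3 (up to 0.36), with Gsta2 and Phip also lost without control 1 and Snhg11 without MASH 3.

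In resmetirom livers against controls, Dio1 rose from 90.9 ± 14.5 to 490 ± 214 CPM (SD, n = 3 each; log2 fold change 2.43 ± 0.35 SE; edgeR adjusted p = 0.0104). Tff3, a trefoil factor of mucosal epithelia, rose from 1.34 ± 0.335 to 73.0 ± 61.8 CPM (adjusted p = 0.00857), Hr rose from 0.473 ± 0.257 to 5.69 ± 5.06 CPM and Fgf21 from 1.56 ± 0.0583 to 21.9 ± 19.9 CPM (adjusted p = 0.0417 and 0.0337). Wfdc16 (7.46 ± 0.97), Gldn (6.04 ± 1.40) and Cdc20 (5.48 ± 1.16) rose, and the clock repressor Bhlhe41 (−3.86 ± 0.60) and Snhg11 (−5.73 ± 0.84) fell (adjusted p = 0.0141, 0.042, 0.0318, 0.0115 and 0.0107). Cfd was at least 43.8-fold lower, at 0 counts against 2.37 ± 0.511 CPM (adjusted p = 0.0381). Mup13 (6.39 ± 1.35), Mup21 (−4.98 ± 0.72) and Hectd2os (−5.71 ± 0.86) also passed, with the same uncertainty as above. In all, 442 genes changed, 197 higher and 245 lower, and 3203 had an unadjusted p below 0.05. When the resmetirom and control livers were fitted without the other groups, 5 genes changed, none of them named here, and 0 with a replicate block. In all 12 livers the count was 37 with no scaling factors (20 higher and 17 lower), 1059 with control 1 and resmetirom 2 left out (493 and 566), 1465 with DESeq2 (656 and 809) and 2136 with limma voom and quality weights. With no scaling factors Mup13, Gldn, Cdc20, Cfd, Bhlhe41, Fgf21 and Hr were lost (0.0588 to 0.149). With control 1 and resmetirom 2 left out Gldn, Cfd and Hr were lost (0.0704, 0.117 and 0.0662), with offsets Cdc20, Hr and Fgf21 (up to 0.0665), and with both changes these 5 (0.139). With limma voom these 5 and Mup13 were lost (0.182), with quality weights Gldn, Cfd and Hr (0.303), with no filter Mup13, Gldn, Cdc20, Cfd and Fgf21 (0.157), and with a replicate block Gldn, Cdc20, Cfd and Hr (0.0734). The count was 214, 182 and 170 without EE 1, EE 2 and EE 3, 192, 181 and 243 without MASH 1, MASH 2 and MASH 3, and 684, 134 and 127 without control 1, control 2 and control 3. It was 216 without resmetirom 2. Dio1, Wfdc16, Tff3, Snhg11, Hectd2os, Mup21 and Bhlhe41 passed in all 12 fits that left out 1 library. Mup13, Gldn, Cdc20, Cfd, Hr and Fgf21 passed in 1 to 5 of them and in none without control 1, control 2, control 3 or EE 3 (up to 0.108). They were also lost without EE 1 (Mup13, Gldn, Cdc20 and Cfd), EE 2 (all but Cfd and Fgf21), MASH 1 (all but Cdc20), MASH 2 (all but Mup13), MASH 3 (Gldn, Cfd, Hr and Fgf21), resmetirom 1 (all but Mup13), resmetirom 2 (Gldn, Cfd and Hr) or resmetirom 3 (Cfd).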

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

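The tests of transcript length and GC content for control 1 and for resmetirom 1 were written down before their results were seen, and the other tests of this part were chosen only after the result was seen.

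Control 1 stood apart from the other controls, with 35.4% mitochondrial counts, Kupffer cell and sinusoidal endothelial medians of −2.197 and −1.546 log2 units from the other controls, and erythroid, neutrophil and platelet medians of 2.879, 3.452 and 2.542 (the latter 2 from fewer than 5 tested genes). Crowding by mitochondrial transcripts as the whole cause is argued against by the highest correlation with another control, 0.886 as scaled (computed with a smaller prior count than the correlations given earlier) and 0.884 with mitochondrial genes removed, while control 2 and control 3 correlated at 0.981. Removing a trend with transcript length and GC content left that value at 0.895. The erythroid, neutrophil and platelet values go with blood in the sample, but blood as the whole cause would have lowered the Kupffer cell markers no more than the hepatocyte median of −0.229, and their upper quartile was −1.493. Blood as a part of the pattern, RNA damage in this liver and a difference in how it was cut or stored were not tested and stay open, as does a difference of the animal itself, and no biological explanation was tested.

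In the fit of EE and MASH alone, 391 genes were higher and 355 lower with EE, and the higher genes had short transcripts rich in GC (median length 1960, GC 53%) and the lower ones long transcripts poor in GC (4884 and 43%). A smooth trend with length and GC, as fitted for the offsets, is argued against as the whole cause by the share of the log2 fold change kept. That share had a median of 0.671 for higher genes (quartiles 0.506 and 0.854) and 0.765 for lower genes (0.547 and 0.952), or 0.672 and 0.76 in the fit with a replicate block. Of the higher genes 75 still passed, with the median log2 fold change going from 0.557 to 0.373 and its SE from 0.108 to 0.102, and of the lower genes 75, from −0.833 to −0.615 (0.171 to 0.146), so calls ended mainly because the changes became smaller. A loss of all cells other than hepatocytes as the cause of the lower genes is argued against by the Kupffer cell median, which lay 0.683 log2 units above the median of 9 other lists (0.467 to 0.846 over the EE livers). The trend stays open as a part or the whole of the cause. For the 1400 higher and 1345 lower genes called with the block, which kept medians of 0.651 and 0.724, the fitted trend stays open as the whole cause too. Their lower quartiles were 0.413 and 0.457, under the bound of 0.5, and 592 and 645 still passed with block and offsets. An effect of EE on expression, the explanation the design gives, stays open beside a batch that follows the groups, which the labels do not rule out.

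Resmetirom 1 stood apart from the other resmetirom livers, with cell cycle, lipid-associated macrophage and extracellular matrix medians of 2.87, 1.76 and 1.60 log2 units from the MASH mean. A larger share of all cells other than hepatocytes is argued against by the sinusoidal endothelial markers, whose upper quartile was 0.194 while the Kupffer cell median was 1.165. A trend with length and GC is argued against by the cell cycle difference from the other resmetirom livers, 2.698 before and 2.648 after its removal, a share of 0.981. An earlier or later time of day is argued against by MASH 1 and EE 1, which like resmetirom 1 had the lowest Dbp of their groups (11.5, 43.8 and 24.2 CPM) but cell cycle medians of −0.517 and −0.489 relative to the other livers of their groups. An injury or a regrowing part of this liver and a macrophage influx were not tested and stay open.

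Counts of splits that gave as many include the real one. A comparison has 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. Only the real split gave any changed genes for MASH against control (2), EE against MASH (1) and EE against MASH alone (746). The same held for resmetirom against MASH (93), EE against resmetirom (43) and EE against control (14). Of the 9 other splits for EE against MASH, 3 part all same-numbered pairs as the real one does, with at most 0 genes and 12 lists, and 6 part 1 pair, with at most 0 genes and 15 lists. A replicate block was run for the real split (5 genes in all 12 libraries and 2745 with EE and MASH alone) and for those 3 splits (at most 0 in each), not for the other 6. For resmetirom against control 2 splits gave as many genes (442, highest other 893), and the larger count came with control 1, resmetirom 2 and resmetirom 3 set against control 2, control 3 and resmetirom 1. For lists, 1 split gave as many for MASH against control (21, highest other 18) and EE against MASH (21, highest other 15). It was 3 splits for EE against resmetirom (25, highest other 25) and 9 for resmetirom against MASH (13, highest other 26). Of 100 splits of 9 libraries, 2 gave as many genes moved back by EE as the real split (1, highest other 1) and 1 as many genes changed by both treatments (1, highest other 0), shares under 0.05. These results are a single gene, Glcci1, the 40 simulations of unchanged groups also gave up to 1 gene for EE, and the counts were 0 without any of 8 and 9 of the libraries, so little rests on these shares. For genes moved back by resmetirom 6 did (1, highest other 35), so chance is not excluded there. In 4 of these splits more genes were called, and in 3 of them (29, 33 and 35 genes) the 3 resmetirom livers stayed together as a group set against mixed control and MASH livers, which points to a structure of the samples in which resmetirom livers stand apart. The 4th gave 2 genes.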

How the results depend on the processing

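Tests with quality weights, offsets, no scaling factors, mitochondrial genes removed, or a block or lists in only the compared groups were chosen after the results. So was leaving out both outlying libraries (control 1 and resmetirom 2), though the kept resmetirom 1 stood apart too. Counts below follow the order MASH against control, EE against MASH, resmetirom against MASH, EE against resmetirom, EE against control and resmetirom against control, and then genes moved back by EE, moved back by resmetirom and changed by both treatments. As reported they were 2, 1, 93, 43, 14 and 442, and then 1, 1 and 1. Except where said, the cause was not tested.

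They stayed within 1.5 times of these with scaling by relative log expression (2, 1, 86, 41, 14 and 463, then 1, 1 and 1) or the upper quartile (2, 1, 94, 44, 13 and 464, then 1, 1 and 1), with the filter at a mean of 1 CPM (2, 1, 86, 35, 14 and 502), with the same calls limited to a log2 fold change of at least 1 in size, without a new test (2, 1, 91, 43, 14 and 358), and with mitochondrial genes removed (2, 1, 92, 45, 14 and 462). The median log2 fold change of all genes stayed within 0.1 of 0 under these scalings. With no scaling factors beyond the library totals it moved to 0.367, −0.322, −0.128, −0.173, 0.0417 and 0.218, and the counts were 1, 1, 38, 12, 0 and 37, then 1, 1 and 1.

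DESeq2 gave 73, 23, 622, 385, 467 and 1465, then 5, 15 and 10. Limma voom gave 1, 0, 100, 30, 9 and 354, then 0, 0 and 0, and with quality weights 564, 1340, 834, 249, 2561 and 2136, then 113, 48 and 258. With no filter on low counts, edgeR gave 34, 8, 243, 176, 117 and 537, then 2, 6 and 4. With only the 2 groups compared, it gave 0, 746, 0, 3, 0 and 5, then 0, 0 and 0, and with offsets as well 0, 183, 14, 6, 3 and 6, then 0, 0 and 1. With a replicate block in these fits it gave 0, 2745, 27, 10, 0 and 0, then 0, 0 and 7, and with block and offsets 0, 1650, 20, 8, 0 and 3, then 0, 0 and 6. These fits hold 6 libraries, so that the wider spread of the control and resmetirom livers does not enter EE against MASH. With length and GC offsets in all 12 libraries the counts were 0, 0, 125, 60, 2 and 296, then 0, 0 and 0. With both outlying libraries left out they were 9, 67, 467, 417, 589 and 1059, then 1, 1 and 18, and with offsets as well 9, 11, 258, 376, 25 and 449, then 1, 1 and 2. With a replicate block they were 2, 5, 112, 19, 17 and 327, then 2, 2 and 3, and for EE against MASH the block in all 12 libraries changed no other call of a gene or list named in the text than those given beside the results. Leaving out each library in turn gave 0 to 6, 0 to 1, 1 to 431, 7 to 138, 0 to 69 and 127 to 684, then 0 to 1, 0 to 2 and 0 to 1.

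Of the 41 lists, 21, 21, 13 and 25 passed in the first 4 comparisons. With an estimated correlation 1, 0, 0 and 0 passed limma camera, and with fry 1, 1, 0 and 0. With both outlying libraries left out 11, 13, 16 and 28 passed, and leaving out each library in turn gave 15 to 24, 11 to 23, 5 to 21 and 18 to 28. They stayed within 1.5 times with relative log expression (22, 22, 13 and 25), no filter (25, 23, 18 and 33), a replicate block (22, 22, 16 and 24), only the compared groups (25, 20, 13 and 24) and a replicate block in these (25, 22, 16 and 25).

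The erythroid list, lower in MASH than in control, reversed with both outlying libraries left out (camera adjusted p = 0.38) and without control 1 (0.41), over a range of 0.002 to 0.41 when 1 library was left out. In resmetirom against MASH, the extracellular matrix list reversed without resmetirom 1 (0.0843, range 4.13e-06 to 0.162 when 1 library was left out), as did the interferon list (0.494, range 4.58e-05 to 0.494). The log2 fold change of Col1a1 in that comparison, 1.18 as reported and not past the test, reversed to −0.39 with quality weights and to −0.93 without resmetirom 1, over a range of −0.93 to 1.65 when 1 library was left out.

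For the 121 pairs of a comparison and a gene named in the text, settings other than leaving out 1 library kept the direction and side of the threshold in 1538 cases, gained a call in 166, lost it in 347 and reversed in 1. Leaving out 1 library kept it in 1095, gained in 26, lost in 330 and reversed in 1. For the 80 list calls, the same counts were 441 kept, 196 lost and 1 reversed in other settings, and 868 kept, 89 lost and 3 reversed when 1 library was left out. In the simulated data, 4% to 14% of 2-fold changes were called in the fit of all 12 libraries, so that changes of that size are mostly missed there.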

Other observations

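The genes of this part were chosen after their values were seen, and no test was run on them beyond those given.

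Clock genes differed between livers of a group. Arntl, the activator of the clock, was at 14.2, 5.80 and 10.2 CPM in MASH 1, EE 1 and resmetirom 1 and at 0.98 to 4.94 CPM in the other 9 livers, while Dbp, an output gene that cycles against it, was at 11.5, 43.8 and 24.2 CPM in those 3 livers and at 55.4 to 123 CPM in the others.

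In the resmetirom livers, Nox4, an oxidase gene, was at 7.90, 12.5 and 10.2 CPM, against 23.7 to 41.1 CPM in the other 9 livers. Cyp17a1, a steroid hydroxylase gene, was at 68.3, 129 and 201 CPM against 2.31 to 55.9 CPM. Sult2a1, a sulfotransferase gene of bile acids and steroids, had 224, 5 and 5 counts in the resmetirom livers and 0 in the other 9. Resmetirom 1 held 43.0 CPM of Gpnmb, 11.6 CPM of Trem2 and 11.5 CPM of Mki67, against at most 8.43, 2.01 and 1.47 CPM in the other 11 livers.

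Genes of the exocrine pancreas had a few counts in resmetirom 2, beside 246 of Cela2a. They were 6 of Amy2a5, 5 of Prss2, 3 each of Cpb1, Ctrb1, Pnlip and Cela3b, 1 of Cpa1 and 0 of Cel. In the other 11 livers these 8 genes had 0 to 2 counts each.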
